A study of Mus musculus with 12 samples.

How the data were processed

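The study profiled mouse bone marrow stem cells that had been separated by flow cytometry into cells without (CD49-) and with (CD49+) surface CD49, a name shared by the integrin alpha subunits 1 to 6. Per the labels, each preparation held about 30 cells of an estimated purity of 97.03%, was taken 0 h after the sort and lysed, and was amplified by PCR into cDNA, of which 100 ul at 0.1 ug/ul was submitted. The labelling protocol instead names total RNA as the starting material, and the sample descriptions, which name cDNA, were followed. The labels do not say which alpha subunit was stained. There were 3 CD49- and 3 CD49+ samples, and each of the 6 cDNA samples was hybridised to 2 Affymetrix chip designs, MOE430A and MOE430B, which gave 12 arrays. Nothing in the labels says whether the 3 samples of a group came from separate animals or sorts, and the design text of the series speaks of 2 samples and 12 replicates, so that p-values measure only the spread between these samples, which may be partly technical.

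The deposited values were linear signals, 1 per probe set, made by the authors with MAS5, per the submitters' processing notes. The MAS5 version and settings are not given in the sources used here. The 2% trimmed mean of the signals was the same on every array (about 1500), and the values were therefore used as deposited, with no further scaling between arrays. The signals came without detection calls. A background bound was therefore set for each array at the highest signal among its Bacillus control probe sets, for transcripts that mouse cells lack. A gene at or under this bound on all arrays of a group has only an upper limit there. For such genes a fold is given as "at least", from the mean log2 signal of the brighter group over the mean of the higher of the bound and the gene's own signal on each array of the dimmer group. Arrays have no read depth, and their number limits the precision. PCR amplification of RNA from so few cells adds variation that the array count does not show.

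MOE430A held 22690 probe sets and MOE430B 22575, of which 64 on each were Affymetrix controls and were left out of the tests. Gene symbols came from the platform's annotation tables, updated through Entrez gene identifiers to the RefSeq gene table of the mouse assembly GRCm38.p6. Of the probe sets on MOE430A, 20380 had 1 symbol, 691 had several and 1555 had none. On MOE430B these numbers were 14661, 245 and 7605. Among the probe sets with 1 symbol, 20351 on MOE430A and 14486 on MOE430B matched the RefSeq table, and 0 symbols needed updating. Probe sets without exactly 1 symbol were not named.

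Signals were transformed as log2(signal + pseudocount), with the 25th percentile of all signals of the chip design as pseudocount (27.0 on MOE430A and 139.8 on MOE430B), so that differences of weakly expressed genes are understated. Probe sets whose mean log2 value lay at or above the median of those means on their chip design were tested (11313 on MOE430A and 11256 on MOE430B). Differences between CD49+ and CD49- samples were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), with Benjamini-Hochberg adjustment within each chip design and a threshold of 0.05. Errors given as SE are the moderated standard errors of that fit. The tables of the 2 chip designs were scaled separately by the authors and were tested separately. For 100 probe sets present on both designs, signals on MOE430B were higher by a median of 3.09 on the log2 scale.

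Before the data were examined, 26 gene lists were fixed (lineage markers, cell cycle phases, metabolism, stress and adhesion), together with the tests, the alternatives and the rule for naming genes. The lists were tested with camera (limma, preset correlation of 0.01) over 12019 genes, each represented by its probe set with the highest mean among the tested ones. Because MOE430B signals ran higher, this choice favours that design. Of the 26 lists, 24 were tested. The natural killer cell list had 3 measured genes, under the minimum of 4, and the sex-linked genes served only as a check. Gene lists were also tested with an estimated correlation and with fry, a rotation test of each list by itself, which does not compare a list with other genes.

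Genes were named by this rule. In each direction the 10 genes with the smallest adjusted p at or under 0.05 were taken, filled up to 10 by the smallest unadjusted p among genes with an absolute log2 difference of at least 1 and no overlap of the groups. The integrin genes Itga1 to Itga6 and Itgb1 were always named. For a list past the threshold its 4 members with the largest statistic in the list's direction were taken, and for every other list the 2 with the smallest p. Stem cell genes with an unadjusted p under 0.05 and the sex-linked genes completed the rule. The rule was applied to genes, each represented by its probe set with the highest mean, and disagreement among its probe sets is stated. Besides the cases given with the results, tested probe sets disagreed in sign for Dnaja1 (2 higher and 1 lower in CD49+ samples), Hspa5 (1 and 2), Psme3 (1 and 1) and Abcc5 (2 and 3).

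The integrin genes were tested in a fit without the filter, with adjustment over their own probe sets. The similarity of samples and the 3' to 5' signal ratio of control genes were compared by exact permutation tests over the splits of 6 samples into 3 and 3, whose smallest p is 0.1. The tube names show 2 submissions. MZ1484 holds 1 sample of each group (replicate 1) and MZ1468 the other 2 of each. The scanner records showed that the submissions were scanned on different days, so that submission and scan day are 1 factor. The MOE430A arrays of MZ1468 were also run on another station than all other arrays, per the file headers. The sample descriptions in these records matched the group labels on all 12 arrays. Alternatives covered the normalization, the pseudocount, the filter, the variance trend, blocks for submission and for consecutive tubes, and leaving out each sample in turn. The choice of probe set per gene was varied for the lists. For the counts of changed probe sets alone, adjustment was also made over both chip designs together. In another alternative for these counts, probe sets with names ending in _s_at, _x_at or _a_at were left out. An analysis of submission MZ1468 alone, the correlations within it by group, the share of probe sets without overlap in other splits and the comparison of the submissions were added after the data were seen.

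The fits were tested on simulated data, in which 200 probe sets per chip design were changed on the measured means and spreads, in 10 simulations of the comparison of CD49+ with CD49- samples. At a log2 change of 4, 19.5% of the changed probe sets were called among 11313 tested on MOE430A and 48.8% among 11256 on MOE430B. At a log2 change of 2, 4.49% and 7.00% were called. The mean estimated sizes were 3.91 and 3.82 for a true 4, and 1.98 and 1.90 for a true 2. False calls made up 6.02% of the calls on MOE430A and 6.07% on MOE430B. A gene list shifted by -2 was called in 10 of 10 simulations over 12026 genes, and 0 other lists were called. The simulated noise was independent between genes and held no submission difference, whereas the estimated correlation of the measured lists reached 0.71. The simulations therefore do not measure false list calls in the real data. The shift of -2 was also larger than the mean of -0.97 of the list that passed.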

Results

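Gene expression was measured in 6 samples of amplified cDNA from sorted mouse bone marrow stem cells, 3 CD49- and 3 CD49+, on 2 array designs that together cover 12019 named genes with a mean signal at or above the median of their design. The comparison asked how the transcriptomes of stem cells with and without surface CD49 differed directly after the sort. Between 39.5% and 61.1% of the probe sets on MOE430A, and between 16.5% and 28.6% on MOE430B, gave signals above the Bacillus control bound of their array. On MOE430B this share was 25.7 ± 2.80% in CD49- and 18.3 ± 1.57% in CD49+ samples (SD, n = 3 each), with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 samples can give. On MOE430A it was 54.3 ± 7.13% and 47.5 ± 7.24% (SD, n = 3 each, exact two-sided permutation p = 0.4). Fewer probe sets were above the bound in CD49+ samples within both submissions, by differences of -7.39 and -6.48 percentage points on MOE430A and of -6.71 and -7.77 on MOE430B (MZ1484 and MZ1468, respectively). The bound itself was on average higher in CD49+ samples. Its means in CD49- and CD49+ samples were 947 and 1330 on MOE430B, without overlap, and 85.3 and 111 on MOE430A. Mean median signals were 383 and 388 on MOE430B and 115 and 101 on MOE430A. The lower share therefore does not by itself show weaker signals.

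The 4 MZ1468 samples resembled each other more than they did the MZ1484 samples. On MOE430A, log2 profiles of MZ1468 samples correlated with each other at 0.74 to 0.88 across probe sets, and with MZ1484 samples at 0.51 to 0.61, while the 2 MZ1484 samples, one of each group, correlated at 0.60. On MOE430B the corresponding values were 0.65 to 0.82, 0.45 to 0.53 and 0.50. On both designs the correlation between the 2 MZ1484 samples thus lay within the range of their correlations with MZ1468 samples. Probe sets are not independent replicates, and these correlations only describe the arrays. The mean correlation within CD49 groups minus that between them was -0.03 on MOE430A and -0.02 on MOE430B (exact permutation p = 0.5 on each, smallest possible p = 0.1). Submission lowers this value by design, since 4 of 6 pairs within groups but 4 of 9 between them cross submissions. Among the 6 splits with 1 MZ1484 sample in each group, the real split had the highest value on both designs (-0.0286 and -0.0194). The lowest of these splits gave -0.0335 on MOE430A and -0.0326 on MOE430B. The p of 0.5 is therefore no evidence against a grouping by sort, and 6 splits are too few for a share under 0.05. Among the 4 MZ1468 samples, the mean correlation was 0.81 within and 0.81 between groups on MOE430A, and 0.73 and 0.73 on MOE430B. On MOE430A the signals of a Y-linked gene also followed the submission. Eif2s3y, a translation initiation factor gene on the Y chromosome, gave signals of 15.4 and 16.2 in the MZ1484 samples and of 3349 to 7413 in the MZ1468 samples, and the brightest Kdm5d probe set gave 1.69 and 15.9 against 145 to 669. A second Kdm5d probe set went the opposite way, with 113 and 119 in the MZ1484 samples and 10.5 to 78.6 in the MZ1468 samples. The third, and that of Eif2s3y on MOE430B, did not part the submissions. Signals of Xist, the transcript of the inactive X chromosome, lay between 3.20 and 57.8 in all samples, under the bound of every array, as did all probe sets of Uty, and Usp9y reached at most 177. For the 100 probe sets present on both designs, the deviations from the probe set means correlated at 0.90 to 0.97 between the 2 arrays of a sample and at most at 0.43 between arrays of different samples, so that all 6 samples matched their own second array.

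Among the genes named by the rule, a set had strong signals in CD49- samples and was at or near background in CD49+ samples. The rule picks genes for small p-values, so that this contrast follows partly from the choice and is no test of a difference. Fgd5, a guanine nucleotide exchange factor used as a marker of haematopoietic stem cells, had mean log2 values of 12.63 ± 0.73 in CD49- and 8.21 ± 0.32 in CD49+ samples (SD, n = 3 each), a difference of -4.42 ± 0.51 (SE), at least 4.67-fold (limma adjusted p = 0.53). Clu, the secreted chaperone clusterin, had means of 12.14 ± 1.84 and 7.22 ± 0.34, and Slamf1, which encodes the stem cell marker CD150, 9.62 ± 1.75 and 5.79 ± 0.67 (SD, n = 3 each). In the test over all probe sets, however, none of these differences passed the threshold. The limma test called 0 of 11313 probe sets on MOE430A (smallest adjusted p = 0.90) and 0 of 11256 on MOE430B (smallest adjusted p = 0.53). At an unadjusted p under 0.05 there were 272 probe sets on MOE430A, 214 of them lower in CD49+ samples, and 414 on MOE430B, 254 of them lower. These were 2.40% and 3.68% of the tested probe sets, under the share of 0.05 that chance alone gives. With the submission as a block the counts were 469 and 556, also not above that share. With single samples left out they were 215 to 521 and 354 to 609, the highest without CD49+ replicate 3 on both designs. The groups did not overlap for 6.92% of probe sets on MOE430A and 9.26% on MOE430B, against the 10% that chance gives for 3 against 3 exchangeable samples. The submissions make that share too high here, and the 5 other splits with 1 MZ1484 sample in each group gave 6.82% to 8.05% on MOE430A and 7.76% to 9.05% on MOE430B.

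**Figure D1:**
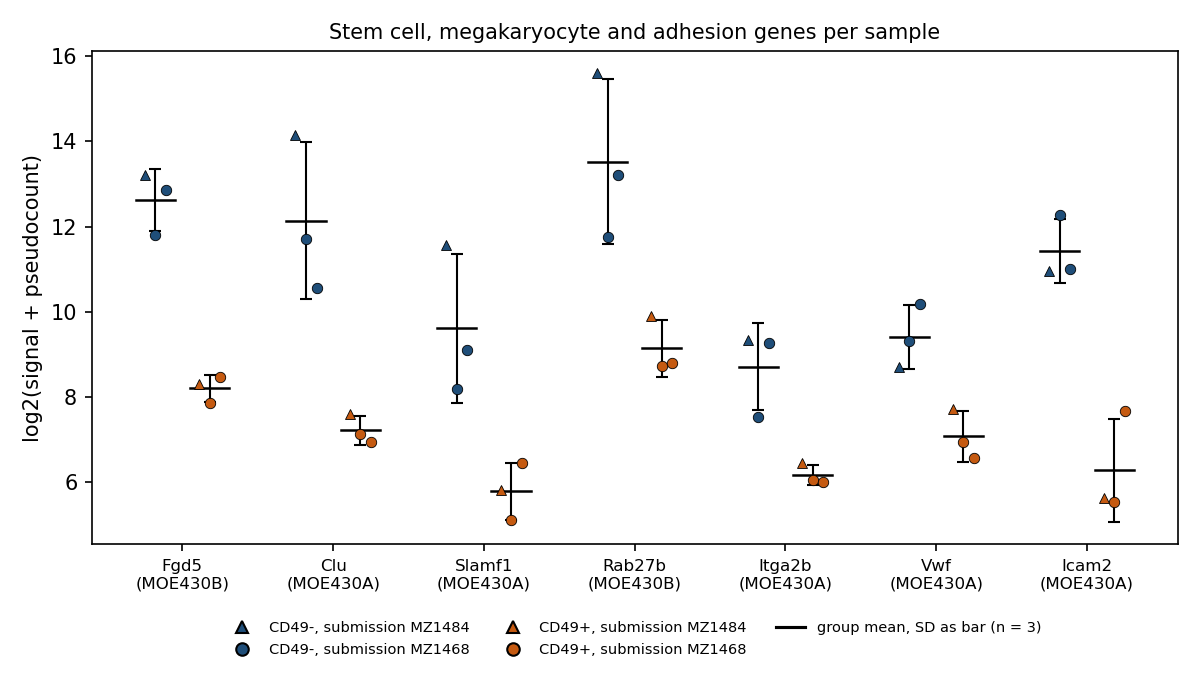
Values of 7 genes as log2(signal + pseudocount) in each of the 6 samples; blue is CD49-, orange CD49+, triangles are submission MZ1484 and circles MZ1468, and the black line and bar are the group mean and SD (n = 3). Only named genes without overlap of the groups are plotted, so that each is higher in all 3 CD49- than in all 3 CD49+ samples. Differences run from -2.33 (Vwf) to -5.13 (Icam2), and none passed the adjusted threshold over all probe sets. For Fgd5, Slamf1, Rab27b and Itga2b all 3 CD49+ arrays are at or below background. Not plotted are Itgb3, also named for the megakaryocyte list, and other probe sets of Rab27b (-0.46 ± 0.49 and -0.33 ± 1.14, SE) and Clu (-3.56 ± 1.62, SE), for which the groups overlap.

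The 10 genes lower in CD49+ samples were picked for the smallest p among those without overlap of the groups. They had log2 differences between -3.03 and -5.69 and unadjusted p-values from limma of 7.66e-05 to 0.00151. All 10 were above the background bound on all CD49- arrays, and 9 were at or below it on all CD49+ arrays. For these 9 only a lower bound of the fold holds. Besides Fgd5 they were the keratin Krt7 (at least 25-fold brighter in CD49- samples), the kinesin light chain Klc1 (at least 19.1-fold), the iron regulator Hfe (at least 12.0-fold), Usp30, a deubiquitinase of mitochondria (at least 9.90-fold), the nucleotide sugar transporter Slc35d2 (at least 7.97-fold), the opsin Opn3 (at least 7.76-fold), the telomere protein gene Tinf2 (at least 4.30-fold) and the ubiquitin ligase Shprh (at least 2.08-fold), with limma adjusted p-values of 0.53 to 1.00. The adhesion molecule Icam2, above background on 1 CD49+ array, differed by -5.13 ± 1.00 (SE). Other probe sets disagreed for 3 of these genes. A second probe set of Usp30 differed by 1.69 ± 1.56, one of Tinf2 by 0.61 ± 2.11, and those of Shprh by 0.06 ± 0.32 and 0.10 ± 0.73 (SE).

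The 10 genes at the other end, higher in CD49+ samples and picked in the same way, had log2 differences of 1.56 to 5.79 and unadjusted p-values from limma of 0.000683 to 0.00629. Of these, 9 were on MOE430B, and for 3 (Gm31087, Cabp7 and 4930428O21Rik) both groups were at or below the background bound on every array. The largest difference was that of the transcript 9130008F23Rik, 5.79 ± 1.04 (SE), with group means of 10.21 ± 1.18 and 16.00 ± 1.23 (SD, n = 3 each). Capn1, a calcium-dependent protease, differed by 4.47 ± 1.15 (SE), at least 9.68-fold, with a limma adjusted p of 1.00. For Capn1, 1 of the 3 CD49+ arrays was at or below the bound, and the difference was 1.94 within MZ1484 and 5.73 within MZ1468. Scly, the selenocysteine lyase, differed by 1.82 ± 0.33 (at least 1.65-fold, limma adjusted p = 0.85) on one probe set and by 0.60 ± 1.29 on another. Morn5, Fam71a, Mroh3 and Pgbd1 were also at or below the bound in every CD49- sample, and as lower bounds Pgbd1 was at least 1.87-fold, Mroh3 at least 1.32-fold and Fam71a at least 1.12-fold brighter in CD49+ samples (limma adjusted p = 1.00 each). For Morn5, Fam71a and Mroh3, 2 of the 3 CD49+ arrays were at or below the bound as well.

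Megakaryocyte and platelet genes were the only list past the threshold, and were lower in CD49+ samples. Of 18 measured members, 14 were lower and 4 higher, with a mean log2 difference of -0.97 and a median of -0.51 (camera, adjusted p = 0.0114 over 24 lists). With an estimated correlation the call was lost (adjusted p = 0.96), as it was with fry (adjusted p = 0.89). None of the members passed over all probe sets, 3 had an unadjusted p under 0.05, and 2 passed when adjusted over the list alone. These were Rab27b, a small GTPase of platelet granule secretion (-4.37 ± 1.07, SE, at least 8.69-fold), and Itga2b, which encodes integrin alpha IIb or CD41 and is also expressed on early progenitors (-2.54 ± 0.65, at least 3.59-fold), with a limma adjusted p of 0.0483 each over the list and of 1.00 each over all probe sets. Both were at or below background on all 3 CD49+ arrays, so that only the bounds hold. Vwf, von Willebrand factor, differed by -2.33 ± 0.78 and Itgb3, the partner of Itga2b, by -2.70 ± 1.56 (-7.15 within MZ1484, -0.48 within MZ1468, and -1.10 without CD49+ replicate 1). Other probe sets of Rab27b differed by -0.46 ± 0.49 and -0.33 ± 1.14. The list's mean difference was -1.31 between the 2 MZ1484 samples and -0.80 within MZ1468, and with the submission as a block the camera adjusted p was 0.0333. Of the 18 members, 8 were lower in CD49+ samples in both submissions and 1 was higher in both, while the others changed sign between submissions. The call was also lost with median centring (adjusted p = 0.13), no filter (mean -0.50, 0.34), the top 25% by signal (0.16), MOE430A probe sets preferred (0.10) and MZ1468 alone (0.18), and without any of 3 single samples. Without CD49- replicate 1 the mean difference was -0.47 (adjusted p = 0.73), without CD49+ replicate 2 it was -0.85 (0.18) and without CD49+ replicate 3 it was -0.92 (0.64). Leaving out CD49- replicate 1 leaves MZ1484 only among CD49+ samples, and this list was higher in MZ1484 by a mean of 0.74. Without CD49+ replicate 2 or 3, MZ1484 also weighs more among CD49+ than among CD49- samples. The share of probe sets above background was also lower in CD49+ samples, by -6.78 percentage points on MOE430A and -7.42 on MOE430B. The background bounds were on average higher in CD49+ samples, and so was the 3' to 5' ratio of Actb on MOE430B, by 1.09.

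Haematopoietic stem cell genes went the same way without passing. Of 39 measured members, 28 were lower and 11 higher in CD49+ samples, with a mean of -0.74 and a median of -0.38 (camera, adjusted p = 0.17; 0.96 with an estimated correlation). None passed over all probe sets, and only Fgd5 passed when adjusted over the list alone (limma adjusted p = 0.00299). Clu (-4.92) and Slamf1 (-3.83 ± 0.96, SE, at least 6.93-fold, limma adjusted p over all probe sets of 1.00) had unadjusted p-values of 0.00413 and 0.00470. Of the 3 other probe sets of Clu, 2 were at or below background on all CD49+ arrays (at least 37.4-fold and at least 39.0-fold, limma adjusted p = 0.90 each), and the third overlapped between the groups (-3.56 ± 1.62, SE). Within MZ1484 the list's mean difference was -0.82 and within MZ1468 -0.69, and with the submission as a block the camera adjusted p was 0.0583. Of the 39 members, 16 were lower in CD49+ samples in both submissions and 8 were higher in both, while the others changed sign between submissions. Without CD49- replicate 2 or CD49+ replicate 1 the list passed, with adjusted p-values of 0.0140 and 0.00114. Without CD49- replicate 1 the mean was -0.35 (adjusted p = 0.88), without CD49+ replicate 2 it was -0.53 (0.64) and without CD49+ replicate 3 it was -0.64 (0.70). Leaving out replicate 1 of a group leaves MZ1484 only in the other group. Since this list was higher in MZ1484 by a mean of 0.93, the fits without a replicate 1 mix group with submission. Fits without another sample do so to a lesser degree, because MZ1484 then weighs more in the group that lost a sample.

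**Figure D2:**
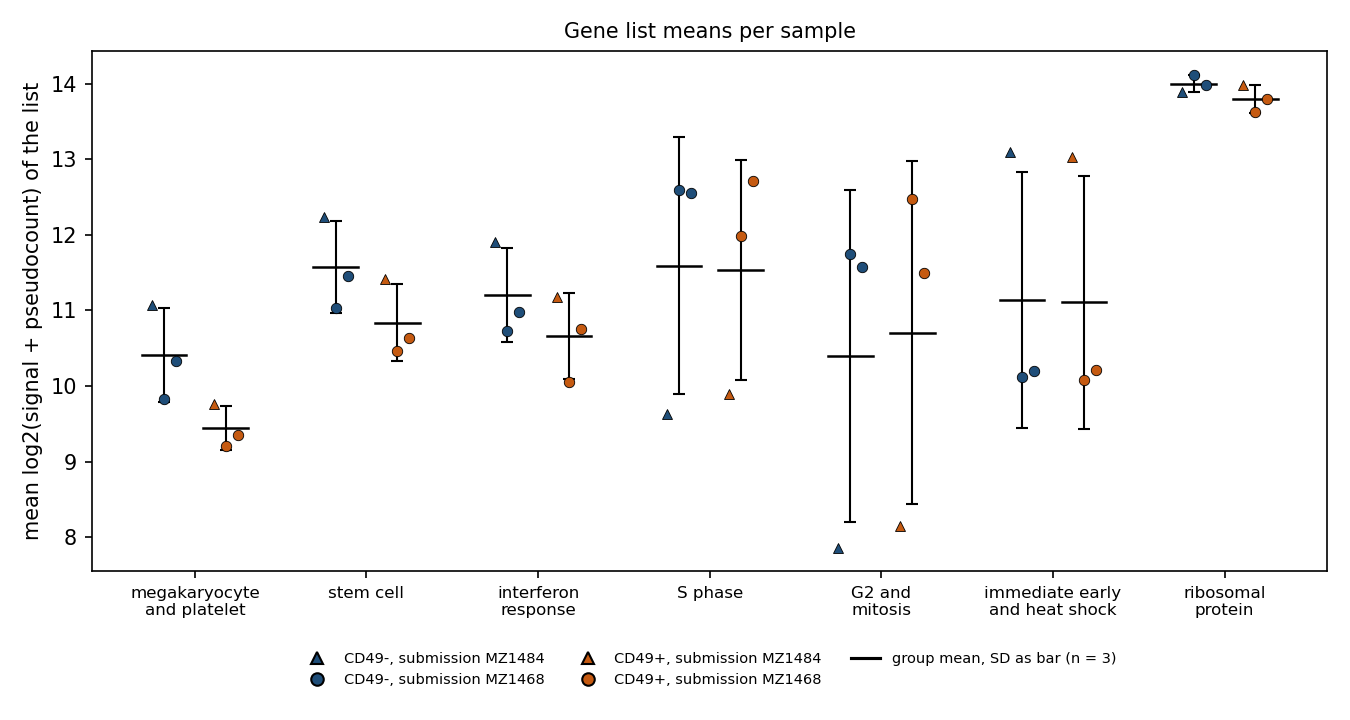
Mean log2(signal + pseudocount) over the measured members of 7 gene lists in each of the 6 samples; colours, symbols, lines and bars stand for the same groups, submissions, means and SDs (n = 3) as in the plot of single genes. Megakaryocyte and platelet genes average 9.83 to 11.07 in CD49- and 9.21 to 9.76 in CD49+ samples, whereas the S phase, G2 and mitosis and immediate early lists separate the 2 MZ1484 samples from the 4 MZ1468 samples.

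No list of markers of other blood lineages passed. Erythroid genes were lower for 8 of 12 (camera, adjusted p = 0.90), with Icam4 at -2.09 ± 0.90 and Urod at 1.48 ± 0.85 (SE). Granulocyte and monocyte genes were higher for 9 and lower for 11 (adjusted p = 0.78), with the Fc receptor gene Fcgr1 at 1.39 ± 0.48 (at least 1.06-fold with 2 CD49+ arrays at background, limma adjusted p = 1.00) and Cd68 at -2.97 ± 1.48. Mast cell and basophil genes were lower for 5 of 8 (adjusted p = 0.92), with Mcpt8 at -2.93 ± 1.57 and Ms4a2 at -0.66 ± 0.57. B cell genes were higher for 7 of 12 (adjusted p = 0.77), with Cd79b at 1.54 ± 1.03 and Fcmr at -0.45 ± 0.32, and T cell genes lower for 5 of 8 (adjusted p = 0.95), with Cd7 at 0.58 ± 0.55 and Lat at -1.47 ± 1.61. Only 3 natural killer cell genes were measured, among them Nkg7 at 2.70 ± 1.58 while Cd160 was at or below background on every array. Genes of multipotent and lymphoid-primed progenitors were higher for 15 of 22 with a mean of 0.21 (adjusted p = 0.42), led by Plac8 (0.92 ± 0.38) and Notch1 (2.17 ± 0.90). Stromal and endothelial genes were higher for 8 of 15, with a mean of -0.14, a median of 0.02 and a test direction of up (adjusted p = 0.95), with Ibsp at 0.80 ± 0.49 and Igfbp7 at -1.11 ± 0.78.

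No cell cycle list passed with all 6 samples. G2 and mitosis genes were higher in CD49+ samples for 26 of 38, with a mean of 0.31 (camera, adjusted p = 0.69), with Bub1b at 2.94 ± 1.28 and Cenpf at 0.89 ± 0.52 (SE). S phase genes split into 17 higher and 18 lower, with a mean of -0.06, a median of -0.11 and a test direction of up (adjusted p = 0.93), with Pola1 at 2.87 ± 1.33 and Rrm1 at -0.64 ± 0.38. Cell cycle inhibitors and quiescence genes were lower for 15 of 24, with a median of -0.23 (adjusted p = 0.95), with Foxo1 at 2.48 ± 1.39 and Ccng2 at 1.35 ± 0.86. Core histone genes were lower for 6 of 8, with a mean of 0.06, a median of -0.11 and a test direction of up (adjusted p = 0.92), with H2bc22 at 2.66 ± 0.97 and H2bc21 at -1.35 ± 1.46. Immediate early and heat shock genes had a mean of -0.03 while the test's direction was up (adjusted p = 0.78), with Dnaja1 at 0.86 ± 0.54 and Hspa5 at -2.23 ± 2.15. Leaving out a sample of MZ1484 leaves 1 group without that submission and moved these lists. Without CD49+ replicate 1, G2 and mitosis genes (mean 1.70) and S phase genes (0.82) passed as higher and interferon response (-0.80) and ribosomal protein genes (-0.29) as lower. Without CD49- replicate 1 the immediate early list passed (0.78) and the G2 and mitosis mean turned negative. Without CD49- replicate 2 the G2 and mitosis list passed (0.99). In that fit MZ1484 weighs more among CD49- than among CD49+ samples. The G2 and mitosis list differed by a mean of -3.82 between MZ1484 and MZ1468, so that this fit also mixes group with submission.

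Interferon response genes were lower in CD49+ samples for 17 of 23, with a mean of -0.54 (camera, adjusted p = 0.42), with Ifit2 at -3.62 ± 1.66 and Trim30a at -1.90 ± 0.93 (SE). Adhesion and homing genes were mixed, 13 higher and 12 lower, with a mean of -0.40 and a median of 0.17 (adjusted p = 0.90). Among them Icam2 passed when adjusted over the list alone and 0 passed over all probe sets, and Pxn was at -1.94 ± 0.84. Glycolysis genes were lower for 11 of 19 (adjusted p = 0.92), with Hk2 at -1.70 ± 1.00 and Pfkfb3 at -2.07 ± 1.26. Oxidative phosphorylation genes were lower for 47 of 82 with a mean of -0.09 (adjusted p = 0.92), with Cox6b2 at -3.29 ± 1.01 and Ndufa5 at -0.42 ± 0.17. Cytosolic ribosomal protein genes had a mean of -0.20, a median of 0.01 and a test direction of down (adjusted p = 0.95), with Rpl39l at -3.51 ± 1.57 (at least 3.99-fold, limma adjusted p = 1.00) and Rps25 at -2.10 ± 1.08. For Rpl39l the groups overlapped, 1 CD49- array was at background, and the difference was 0.75 within MZ1484 and -5.64 within MZ1468. Proteasome genes were higher for 28 of 47 with a mean of 0.14 (adjusted p = 0.42), with Psmd7 at 2.04 ± 0.97 and Psme3 at 2.63 ± 1.44. Hox cluster genes were lower for 9 of 12 (adjusted p = 0.78), with Hoxb2 at -1.94 ± 1.53 and Hoxa5 at -1.78 ± 1.58. Dye efflux transporters were lower for 4 of 7 (adjusted p = 0.78), with Abcc5 at -0.85 ± 0.60 and Abcc1 at -1.67 ± 1.27. Integrin subunits other than alpha 1 to 6 were lower for 7 of 10 (adjusted p = 0.77), of which Itga2b and Itgb3 also belong to the megakaryocyte list. Median centring of the arrays moved the median difference of all MOE430A probe sets from -0.07 to 0.18, and with it the means of the S phase, quiescence, glycolysis, immediate early, stromal, ribosomal protein and oxidative phosphorylation lists turned positive.

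No transcript of the integrins that carry the CD49 name passed between the sorted groups. Itga4 and Itga6 had mean log2 values of 12.87 ± 1.83 and 11.45 ± 1.38 in CD49- and 12.77 ± 1.49 and 11.25 ± 1.08 in CD49+ samples (SD, n = 3 each). Itga2 was near background in all samples, with signals of 13.3 to 125, and differed by 0.19 ± 0.63 (SE). The differences were -0.80 ± 0.58 for Itga1, 0.83 ± 0.81 for Itga3, -0.10 ± 1.17 for Itga4, -1.21 ± 1.12 for Itga5, -0.19 ± 1.00 for Itga6 and -0.15 ± 0.72 for the beta subunit Itgb1. Other probe sets of Itga1, Itga3, Itga5, Itga6 and Itgb1 had the opposite sign. One of Itga5, at or below background on every array, differed by 1.04 ± 0.49 (SE) without overlap of the groups. The signs of Itga4 and Itgb1 turned with quantile normalization, and those of Itga2, Itga4, Itga6 and Itgb1 when single samples were left out. Over the 17 probe sets of the 6 alpha genes, 7 were higher and 10 lower in CD49+ samples, 0 had an unadjusted p under 0.05 in limma (smallest 0.0718) and 0 passed when adjusted over the list alone (smallest adjusted p = 0.94) or over all probe sets. On every array, 6 of the 17 were at or below the background bound. The arrays therefore gave no check of the sort labels from RNA.

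**Figure D3:**
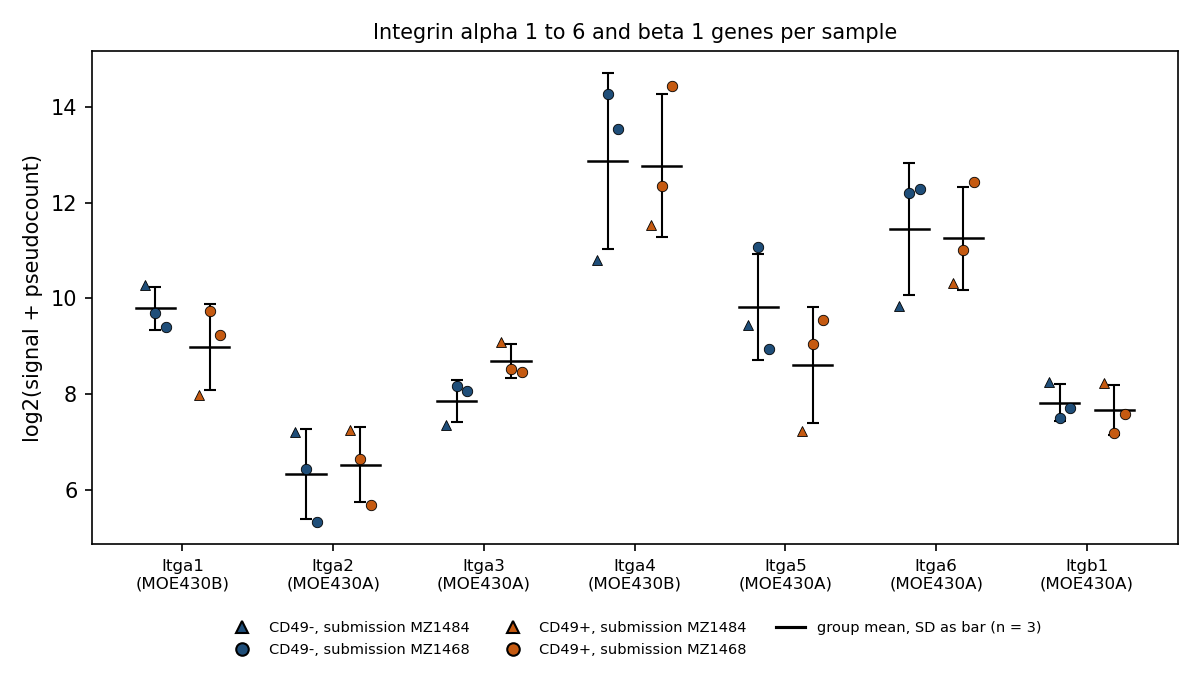
Values of the integrin alpha 1 to 6 genes and Itgb1, each by its brightest probe set, as log2(signal + pseudocount) in each of the 6 samples; colours, symbols, lines and bars stand for the same groups, submissions, means and SDs (n = 3) as in the plot of single genes. The groups overlap for every gene but Itga3, which differs by 0.83 ± 0.81 (SE), the differences of Itga4 and Itgb1 turn sign with quantile normalization, and Itga4 and Itga6 are lower in both MZ1484 samples.

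Control genes had more signal at the 3' than at the 5' end. The mean log2 ratio of 3' to 5' signal of Actb and Gapdh on MOE430A was 4.93 ± 0.90 in CD49- and 5.73 ± 1.99 in CD49+ samples, and on MOE430B 4.81 ± 0.47 and 5.34 ± 1.58 (SD, n = 3 each). The exact two-sided permutation p was 0.6 on each design (smallest possible p = 0.1), and the differences of 0.80 and 0.53 were smaller than the SD of the CD49+ samples. The ratio of Actb alone did part the groups on MOE430B, with 2.55 ± 0.78 in CD49- and 3.64 ± 0.20 in CD49+ samples (SD, n = 3 each, exact two-sided permutation p = 0.1, the smallest possible). On MOE430A the ratios of Actb overlapped between the groups (difference 0.73, exact p = 0.6), and those of Gapdh differed by 0.86 on MOE430A and -0.04 on MOE430B.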

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

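The analyses of submission MZ1468 alone were chosen after the data were seen. No probe set passed on either chip design under any of the 19 alternatives, with smallest adjusted p-values of 0.328 on MOE430A and 0.0747 on MOE430B, both without CD49- replicate 1. No integrin probe set passed under its 17 alternatives. Of the 74 named genes, 66 kept their direction under all alternatives run for them, and none of the 74 passed under any. The exceptions were Lat, Hspa5, Abcc1, H2bc21, Itga2, Itga4, Itga6 and Itgb1. Megakaryocyte and platelet genes were lower in CD49+ samples under all 20 alternatives and passed in 10, with adjusted p-values from 0.000532 to 0.963. The submission block and the scan-day block are the same fit, but are counted separately in all these counts of alternatives. The mean difference of this list, no longer past the threshold, was -0.76 with median centring, -0.50 with no filter, -1.24 in the top 25% by signal, -0.78 in MZ1468 alone, -0.74 with MOE430A probe sets preferred, and -0.97 with an estimated correlation or fry, which test the same values. In each of these settings 0 lists passed. Leaving out 1 sample at a time gave means of -1.25 to -0.47 for this list and 0 to 6 lists past the threshold. Fewer samples or genes were tested in some of these settings. Every fit that leaves out 1 sample mixes group with submission, and those without a replicate 1 sample do so most. Otherwise the cause was not tested. With consecutive tubes as a replicate block, 0 probe sets passed on either design and 1 list did (mean -0.97, adjusted p = 0.0296). Deviations from the group means correlated within these pairs at 0.324, 0.127 and 0.224 on MOE430A and at 0.265, 0.0915 and 0.225 on MOE430B, and 2 of the 3 pairs matched best with their own number. Pair 1 is also submission MZ1484. Within MZ1468 the difference between the 2 samples of a group correlated between groups at -0.00950 on MOE430A and 0.0673 on MOE430B, and the tube numbers were not taken to pair the samples. Signals near background limit the weakest genes to bounds.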

Other observations

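The comparison of the submissions, the platelet transcripts and the tests by matched lists, list members and hybridisation controls were chosen after the results were seen, while the counts over other splits of the samples were planned. The genes named for the submissions were chosen after their values were seen. With CD49 group as a covariate, 839 of 11313 probe sets on MOE430A differed between the submissions (131 higher and 708 lower in MZ1484, limma, adjusted p at or under 0.05), as did 45 of 11256 on MOE430B (11 higher and 34 lower). The largest count among the other 14 of the 15 ways to pick 2 of the 6 samples was 83 on MOE430A and 11 on MOE430B. Cell cycle genes fell in MZ1484. G2 and mitosis genes differed by a mean of -3.82, and 18 of 38 were lower over all probe sets, 27 when adjusted over the list alone (camera, adjusted p = 3.99e-15, and 0.20 with an estimated correlation). Among them were Mki67, a proliferation marker (at least 102-fold), Top2a, a topoisomerase of dividing cells (at least 66.2-fold), and the cyclin Ccna2 (-5.93 ± 0.68, SE). S phase genes differed by a mean of -2.70, with 7 of 35 lower over all probe sets and 14 when adjusted over the list alone (camera, adjusted p = 1.81e-07, and 0.09 with an estimated correlation), among them the replication helicase gene Mcm5 (at least 64.3-fold). The limma adjusted p-values of these 4 genes were 0.0212 to 0.0359. Where a bound is given, all arrays of the dimmer submission were at or below background, and the bound is taken from signals without the pseudocount.

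The list of immediate early and heat shock genes was higher in MZ1484 by a mean of 2.91, with 12 of 31 higher and 1 lower over all probe sets, and 17 higher and 1 lower when adjusted over the list alone (camera, adjusted p = 1.16e-11, and 0.09 with an estimated correlation). None of the 12 was a heat shock gene, and the 1 lower was Hsph1, which is one (at least 75.2-fold, limma adjusted p = 0.0212). Other heat shock genes did not pass, with Hspa5 at -3.29 ± 2.03 (SE), Hsp90aa1 at -0.70 ± 0.41 and Hspe1 at 0.04 ± 0.11. The transcription factor genes Fosb (at least 128-fold), Klf4 (at least 64.5-fold), Egr3 (at least 44.9-fold) and Nr4a3 (at least 144-fold) were high in both MZ1484 samples, as were the activation marker Cd83 (at least 291-fold) and the class II antigen presentation genes H2-Eb1 (at least 158-fold) and Cd74 (4.36 ± 0.68, SE). The lectin gene Clec4d (at least 125-fold) and the chemokine gene Ccl9 (at least 43.1-fold) were lower there. The limma adjusted p-values of the genes from Fosb to Ccl9 were 0.0128 to 0.0268. Stem cell genes were higher in MZ1484 by a mean of 0.93 (adjusted p = 9.06e-05, and 0.12 with an estimated correlation). Of 24 lists, 11 passed with the preset and 0 with an estimated correlation. The 3 lists of cell cycle and immediate early genes passed in the same direction under all 6 alternatives, but the counts of probe sets moved. Median centring gave 2410 on MOE430A, 82.4% of them higher in MZ1484 against 15.6% with deposited values, because it shifted the median of all probe sets from -0.43 to 0.96, and quantile normalization gave 760, 23.0% of them higher. Counts were 559 with the pseudocount at the median and 319 with no filter. On MOE430B they were 15 with median centring (60% higher, against 24.4%), 12 with the pseudocount at the median (66.7% higher), 95 with a pseudocount of 1 (8.42% higher) and 149 in the top 25% by signal.

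The cell cycle difference is a pattern for which technical causes can be weighed. On MOE430A the MZ1484 arrays had a mean of 43.2% of probe sets above background against 54.8% in MZ1468, a mean upper quartile of signals of 441 against 1146, and log2 ratios of 3' to 5' Actb signal of 1.39 and 2.90 against 3.14 to 4.31. On MOE430B the means were 22.2% against 21.9% and 886 against 998, and the ratios overlapped. The 11 G2 and mitosis genes measured on MOE430B also differed, by a mean of -2.36 (SE 0.741 over the genes) against a median of -0.06 for all probe sets there. Their fall thus went beyond that of the design as a whole. This cannot exclude lower detection, because the genes belong to a list already known to be lower and the SE treats them as independent. The similar shares on MOE430B also rest on bounds with means of 1024 in MZ1484 and 1196 in MZ1468. For the immediate early list, the 12 members past the threshold as higher are the pattern itself, so that their count is no further test of lower detection. Lower detection stays open as a cause of the shift of the cell cycle genes. The bacterial controls added at hybridisation were higher in MZ1484, by 0.678 (SE 0.126) on MOE430A and 0.672 (SE 0.159) on MOE430B. They cannot exclude a difference in hybridisation or scanning, because the common trimmed mean removes a change of signal across a whole array. Scan day, and on MOE430A the station, also followed the submission, so that this cause stays open. Cells in cycle in the MZ1468 samples stay open. The S phase list lay at percentile 0 among 10000 random lists matched on signal, but was known to be lower before this was computed, so that the value decides nothing. The quality and amplification of the RNA, the sort, the animals, their sex and the handling before lysis may each differ between submissions, and stay open as causes.

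The lower megakaryocyte and platelet genes of CD49+ samples are the second pattern. Fewer probe sets above background in those samples stay open as a cause, although the bound was also on average higher there. The list's mean lay at percentile 0.11 among 10000 random lists matched on signal, whose mean was -0.16, but the list was weighed because it was already lower than other genes, so that the value decides nothing. Platelets or megakaryocytes carried into the CD49- samples stay open. The mean difference of 6 abundant platelet transcripts, 4 of them among its 18 measured members, was 0.187 (SE 0.530), but 4 of the 6 were at background on at least 2 of 3 CD49- arrays and could hardly be lower in CD49+ samples, and Pf4, the only one above it on all 3 (2561 to 5929), differed by -2.10 ± 1.67 (SE, in the fit without the filter), by 0.32 in MZ1484 and by -3.32 in MZ1468. Ppbp and Treml1 went the other way within MZ1484, with signals of 1516 and 2198 in the CD49+ and 9.91 and 88.8 in the CD49- sample, and were at background in the other CD49+ samples. The CD49 sort itself, the biological explanation that the design names, also stays open and was not tested apart from these.

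The 10 splits of 6 samples into 3 and 3 are too few for a share under 0.05. The real split gave 0 probe sets on MOE430A (highest other 88) and 0 on MOE430B (highest other 30), a count that 10 of 10 splits reach by necessity and that therefore tests nothing. In 5 of 10 splits at least 1 list passed (highest other 10). The 4 splits that put both MZ1484 samples into 1 group gave 3 to 10 lists and 640 to 1453 probe sets at an unadjusted p under 0.05 on MOE430A, which points to a structure of the samples, while the 6 that part them gave 0 to 1 lists. Among these 6 the real split was the highest, with 1 list against 0 in each other, 272 probe sets against at most 262 on MOE430A and 414 against at most 390 on MOE430B, and 6 splits are too few for a share under 0.05 as well. With the submission as a block the real split gave 0 probe sets and 1 list.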
